A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

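Total RNA from log-phase fission yeast (Schizosaccharomyces pombe), grown in YEA, a rich medium, at 30 °C, was sequenced on an Illumina HiSeq instrument. There were 4 libraries: 2 from wild type (WT) cells and 2 from cells called Y41F. The labels do not name the protein that carries the substitution. From what is known of the study, Y41F is taken here as a change of tyrosine 41 of histone H3 to phenylalanine. Both WT libraries carry the same strain name and the 2 Y41F libraries carry different ones. The labels do not say whether the WT libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical within WT and, within Y41F, includes any difference between the 2 strains.

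Each library has a deposited gene table with an RSEM-type expected count, which need not be a whole number, and an FPKM value per gene, per the file headers. The submitters' processing notes name RSEM, Bowtie and BWA and the genome build ASM294v2, without versions or roles. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes may share reads. The gene lengths in the deposited tables are all multiples of 3, so they are coding lengths. The tables list only genes above 0, and a gene listed in another library was taken as 0 where it was missing. In all, 5133 genes were listed in at least 1 library and 5107 in all 4. Of these identifiers, 5100 matched the ASM294v3 annotation, which gave a symbol for 4253. As the builds differ, that annotation was used for names, for which genes neighbour each other and for membership of the position-based lists, and no coordinates are given.

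Library totals were between 20845572 and 23616464 expected counts. Libraries of 1 group were not duplicates of each other: the chi-square per degree of freedom over genes was 43.6 for the WT pair and 64.0 for the Y41F pair, where sampling noise alone gives about 1. Intervals and floors from counts cover counting error only.

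Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default expression filter, which removed 57 genes and left 5076. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are Y41F over WT on the log2 scale. Their standard errors (SE) were derived from the fold change and its F statistic. Expression levels are CPM, counts scaled by TMM to a common library size, given as mean ± SD of 2 libraries. On data simulated from these means and dispersions (5076 genes, 200 changed in each of 5 simulations), edgeR recovered 40% of genes changed 1.5-fold, 86% at 2-fold, 98% at 4-fold and 99.6% at 8-fold, and 7.9% of its calls were false. DESeq2 1.42.0 recovered 55.6%, 89.6%, 98.4% and 98.4%, with 13.9% false calls. Genes varied independently in these simulations, without any shift shared between libraries. More genes were changed in them than edgeR called in the measured data, which eases the adjusted threshold. These shares therefore need not hold for the measured data.

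Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 24 lists. The same test with an estimated correlation, and fry, were run beside it. The lists cover ribosome biogenesis, ribosomal proteins, nuclear-encoded oxidative phosphorylation, iron uptake, the core environmental stress response, heat shock proteins and chaperones, hexose transport and glucose repression, nitrogen starvation and transport, phosphate and thiamine, meiosis and sporulation, M and P mating type genes, MBF cell cycle genes, mitosis and cell separation, kinetochore and cohesin, DNA damage and replication stress, histones, heterochromatin and RNAi factors, flocculation and adhesion, auxotrophic marker genes, mitochondrially encoded genes, Tf2 retrotransposons, subtelomeric genes and pericentromere-flanking genes. Subtelomeric genes are those with any of 11 systematic name prefixes. Pericentromere-flanking genes lie within 75 kb of a centromere's middle. Of 500 list entries given by name, 29 were not analysed here, among them ura4 and most genes of the mating-type cassettes. They matched no single gene in the deposited tables or, for rps3 in the mitochondrial list, only a nuclear gene. As those tables list only genes above 0, an unmatched name may also mean a gene without counts. No name fixed for the mitochondrially encoded list matched a gene with the SPMIT prefix. That list was therefore made from the 10 genes with this prefix after the identifiers were seen, and 6 of them passed the filter. Other lists were fixed before the data were examined, as were the tests, the alternatives unless said otherwise, and the rule for naming genes.

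By that rule the text may name the 12 called genes with the largest change in each direction (filled by smallest p) among genes with a mean of at least 5 CPM and no overlap between groups, the called genes with the smallest p, all histone H3 and H4 genes and auxotrophic marker genes, and, per list, up to 4 called members or otherwise the 2 with the highest mean. Other genes were chosen after their values were seen, and the text says so. Near-identical copies, among them the Tf2 elements, the histone genes and many subtelomeric genes, share reads, and their separate values are uncertain: 30 tested genes in 12 sets had the same counts, after rounding, in all libraries.

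Alternatives were DESeq2 size factors or library size in place of TMM, other low-count filters, DESeq2's Wald test, limma-voom, limma on the deposited FPKM values as log2(FPKM + 1), with pseudocounts of 0.1 and 5 and without the filter at a mean FPKM of 1, the library number as a block, and leaving out each library in turn. Tables were joined with Python 3.11.15 and pandas 2.3.3.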

Results

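The data are gene-level RNA-seq measurements of fission yeast in log phase, from 2 WT and 2 Y41F libraries. The total expected count was 22260430 and 20845572 in WT libraries 1 and 2, and 23616464 and 22773955 in Y41F libraries 1 and 2. Each library listed between 5120 and 5129 genes, and the 10 most abundant genes took between 12.5% and 13.3% of the counts. Across genes, log2(CPM + 1) correlated at r = 0.990 between the WT libraries and at 0.986 between the Y41F libraries. Library 1 of WT and of Y41F correlated at 0.989 and library 2 of each at 0.991. The first principal component, with 45.8% of the variance, separated the libraries numbered 1 from those numbered 2, and the next, with 38.8%, separated WT from Y41F.

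The series has 1 comparison, the transcriptome of Y41F cells against that of WT. The gene yhb1 (SPAC869.02c), which encodes a nitric oxide dioxygenase, rose in Y41F, from 88.5 ± 2.62 to 236 ± 4.46 CPM (SD, n = 2 per group), a log2 fold change of 1.42 ± 0.08 (SE; edgeR adjusted p = 0.0215). It was the only gene of 5076 that edgeR called, so 1 gene was called higher and 0 lower. Among genes with a mean of at least 5 CPM and no overlap between the groups, the next by p were also higher in Y41F but missed the threshold, with edgeR adjusted p between 0.0693 and 0.0986. SPCC737.04, of unknown function, had a log2 fold change of 2.06 ± 0.17, and went from 13.6 ± 0.998 to 57.0 ± 10.7 CPM. The maltase gene mal1 (SPBC1683.07) had 1.26 ± 0.12 and the hexose transporter gene ght4 (SPBC1683.08), its neighbour, 0.79 ± 0.09.

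Of the other genes among these 12, gcd1 (SPCC794.01c), for a glucose dehydrogenase, had a log2 fold change of 1.34 ± 0.15. The gene for transcription factor Rsv2, rsv2 (SPBC1105.14), had 0.86 ± 0.10 and pun1 (SPAC15A10.09c), for a membrane protein of the SUR7 family, 0.88 ± 0.09. A stretch of chromosome III held SPCC417.09c at 1.07 ± 0.11, SPCC417.11c at 1.16 ± 0.11 and SPCC417.12 at 1.09 ± 0.12. They are annotated as a transcription factor, an aminotransferase and a carboxylesterase. SPBC19C7.04c and SPAC1952.04c, of unknown function, had 1.82 ± 0.19 and 0.86 ± 0.10.

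**Figure D1:**
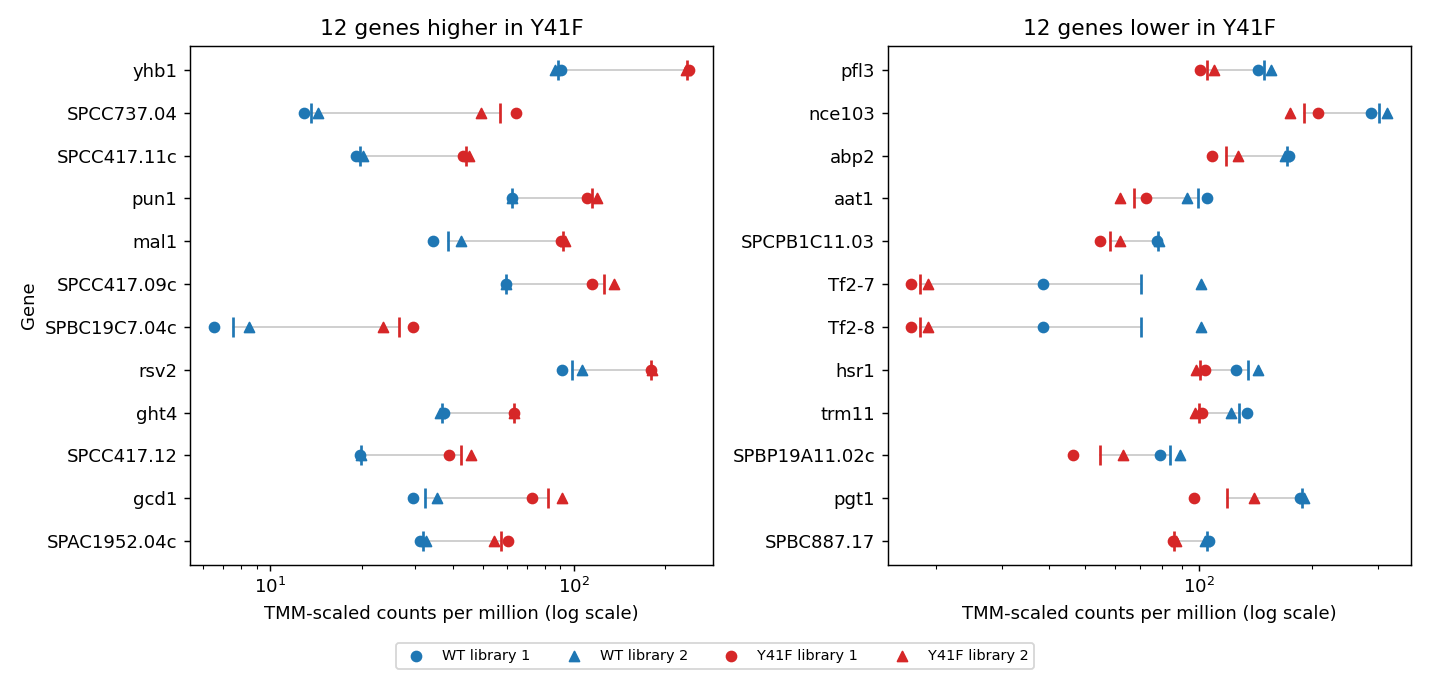
TMM-scaled CPM on a log axis for the 12 genes named as higher and the 12 named as lower in Y41F, with circles for library 1, triangles for library 2, blue for WT, red for Y41F and a vertical tick at each group's mean. For yhb1, the only called gene, the WT libraries lie at 90.4 and 86.7 and the Y41F libraries at 239 and 233, while for Tf2-7 and Tf2-8 the WT libraries lie far apart, at 38.5 and 102.

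No gene was called lower. Among genes with a mean of at least 5 CPM and no overlap between the groups, the 12 lower ones with the smallest p had edgeR adjusted p between 0.283 and 0.495. They include nce103 (SPBP8B7.05c), annotated as a carbonic anhydrase, at a log2 fold change of -0.66 ± 0.12, and pgt1 (SPAC29B12.10c), for a glutathione transporter, at -0.66 ± 0.18. The amino acid permease gene aat1 (SPBC359.03c) had -0.57 ± 0.12, the cysteine transporter gene SPCPB1C11.03 -0.42 ± 0.10 and the transporter gene SPBC887.17 -0.29 ± 0.08. The cell-surface glycoprotein gene pfl3 (SPBC947.04) had -0.50 ± 0.09 and abp2 (SPBC1861.02), for a protein that binds replication origins, -0.54 ± 0.10. The transcription factor gene hsr1 (SPAC3H1.11) had -0.42 ± 0.10, the tRNA methyltransferase gene trm11 (SPBC16D10.02) -0.36 ± 0.09 and SPBP19A11.02c -0.62 ± 0.16. The retrotransposon genes Tf2-7 (SPAC13D1.01c) and Tf2-8 (SPAC19D5.09c) each had -1.95 ± 0.44, with identical counts, so they are 1 measurement and not a pair. Their WT libraries lay far apart, at 38.5 and 102 CPM, against 17.25 and 19.05 in Y41F, so the size of the change leans on WT library 2.

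At an unadjusted p under 0.05, edgeR gave 340 genes, where about 254 would be expected by chance, 249 of them higher and 91 lower (73.2% higher). The share higher was 87.6% with library size as the only scaling and 64.9% with DESeq2, but without Y41F library 2 it was 41.7% (275 of 659 genes), so most were then lower. The libraries of the groups did not overlap for 37.2% of genes, where chance gives 33.3%. Without WT library 1 edgeR called 0 genes (168 at an unadjusted p under 0.05) and yhb1 had an adjusted p of 0.242, and without WT library 2 also 0 (262), with 0.381 for yhb1. Without Y41F library 1 it called 65 genes and without Y41F library 2 it called 197, and DESeq2 called 68 with all 4 libraries, 62 higher and 6 lower.

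A substitution of 1 amino acid need not alter transcript levels, so the counts of the histone genes do not check the labels, and reads of near-identical copies may be split between them. The histone H3 genes hht1 (SPAC1834.04), hht2 (SPBC8D2.04) and hht3 (SPBC1105.11c) had log2 fold changes of 0.12 ± 0.13, -0.06 ± 0.09 and 0.18 ± 0.10. The histone H4 genes hhf1 (SPAC1834.03c), hhf2 (SPBC8D2.03c) and hhf3 (SPBC1105.12) had 0.07 ± 0.19, 0.02 ± 0.10 and 0.07 ± 0.12. None passed the test (edgeR adjusted p from 0.797 to 0.977), and the histone list as a whole (11 genes, mean 0.04, adjusted p = 0.881) was not called. Its most abundant members, htb1 and hta2, had 0.05 ± 0.10 and 0.03 ± 0.13.

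Subtelomeric genes lie near the chromosome ends, where some of the chromatin is silent, though not all of them were silent in WT (yhb1 had 88.5 CPM). As a group they were higher in Y41F (101 tested, mean log2 fold change 0.40, median 0.18, camera adjusted p = 8.32e-10, or 0.512 with an estimated correlation). Of them 68 had a fold change above 0 and 33 below it, and yhb1 alone was called over all genes. Adjusted over the list alone, 13 passed, 11 higher and 2 lower. Besides yhb1, mal1 and ght4, the higher ones include, chosen after their values were seen, the sulfate transporter gene sul2 at 1.03 ± 0.18 and frp1, for a ferric reductase, at 1.80 ± 0.39. SPBCPT2R1.02, chosen after its values were seen, had 0 counts in both WT libraries and 76 and 85 in the Y41F libraries, at least 48.3-fold higher against a floor of 3 counts over the group, though reads shared with other copies enter its counts. With that gene at its bound the list's mean was 0.36 and its median 0.18. The lower ones, chosen after their values were seen, were SPAC977.05c at -3.52 ± 0.69 and SPAC750.08c, annotated as a malic enzyme, at -2.04 ± 0.42, both under 4 CPM in every library. Without Y41F library 2 the list's mean was -0.03, against a median of 0.17 and a camera adjusted p of 7.04e-04, and without WT library 2 the mean was 0.90. On log2(FPKM + 5) the mean was 0.24, and between libraries of 1 group (library 2 over library 1) the list differed by a mean of 0.38 (median 0.08) in WT and 0.40 (median 0.22) in Y41F, means about as large as that between Y41F and WT.

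Iron uptake genes were higher as a group (18 tested, mean 0.67, median 0.18, camera adjusted p = 8.43e-06; adjusted p = 0.588 with an estimated correlation). None was called over all genes, and shu1 and frp1 passed when adjusted over the list alone. The haem-uptake gene shu1 had 1 and 2 counts in WT and 110 and 35 in Y41F, a ratio of 43.5 (95% exact interval 14.6 to 213, counting error only). The iron transport genes fio1 and str1 had 0.92 ± 0.23 and 0.93 ± 0.29. Y41F libraries 1 and 2 lay apart, at 29.2 and 45.8 CPM for fio1, 119 and 201 for str1, and 30.7 and 68.0 for frp1. These 4 were chosen after their values were seen, while the most abundant members, abc4 and the siderophore synthetase gene sib1, had 0.00 ± 0.09 and 0.21 ± 0.11. The list's mean was 0.41 with a filter at 10 CPM and 0.35 on log2(FPKM + 5), with medians of 0.17 in both and the call kept. Between libraries of 1 group (library 2 over library 1) the list differed by a mean of 0.04 (median -0.03) in WT and 0.29 (median 0.21) in Y41F.

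Genes of the core environmental stress response were higher as a group (35 tested, mean 0.28, median 0.16, camera adjusted p = 2.17e-05; adjusted p = 0.588 with an estimated correlation). None was called over all genes, and rsv2, pyp2 and hri1 passed when adjusted over the list alone. The phosphatase gene pyp2 and the kinase gene hri1, chosen after their values were seen, had 0.98 ± 0.21 and 0.84 ± 0.12. The most abundant members, tpx1 and rds1, had -0.03 ± 0.13 and 0.18 ± 0.57. Without WT library 1 the list's mean was 0.11 and the call was lost (camera adjusted p = 0.141), without WT library 2 it was 0.60 and without Y41F library 2 0.06, and this list also differed between libraries 1 and 2 of each group, by a mean of 0.49 (median 0.21) in WT and 0.30 (median 0.05) in Y41F (library 2 over library 1).

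Hexose transport and glucose repression genes were higher as a group (30 tested, mean 0.36, median 0.13, camera adjusted p = 4.35e-05; adjusted p = 0.512 with an estimated correlation). None was called over all genes, and mal1, ght4 and gut2 passed when adjusted over the list alone. The glycerol-3-phosphate dehydrogenase gene gut2, chosen after its values were seen, had 0.53 ± 0.12. The glucose transporter gene ght1 and the glycerol dehydrogenase gene gld1, also chosen after, had 2.52 ± 0.67 and 2.25 ± 0.72, mostly from Y41F library 1, without which they had 1.12 and 0.66. The most abundant members, tdh1 and pdc101, which belong to glycolysis and fermentation, had 0.01 ± 0.13 and -0.06 ± 0.13. Without WT library 2 the list's mean was 0.60 and without Y41F library 2 0.22, and it differed between libraries 1 and 2 by a mean of 0.33 (median 0.10) in WT and 0.07 (median 0.00) in Y41F (library 2 over library 1).

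Meiosis and sporulation genes were higher as a group (37 tested, mean 0.24, median 0.18, camera adjusted p = 0.0065; adjusted p = 0.700 with an estimated correlation). None passed over all genes or adjusted over the list alone. Between libraries of 1 group (library 2 over library 1) the list differed by a mean of 0.12 (median 0.11) in WT and 0.17 (median 0.16) in Y41F. Its most abundant members, mde4 and the cyclin gene cig2, had -0.03 ± 0.10 and -0.18 ± 0.11, against the direction of the list. Without Y41F library 2 the mean was 0.14 and the call was lost (camera adjusted p = 0.170), as it was on log2(FPKM + 5), with a mean of 0.16 (camera adjusted p = 0.0769).

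Ribosome biogenesis genes were lower as a group (47 tested, 46 of them with a fold change below 0, mean -0.25, median -0.26, camera adjusted p = 1.72e-11; adjusted p = 0.700 with an estimated correlation). None passed over all genes or adjusted over the list alone. The nucleolar genes gar2 and nop56 had -0.31 ± 0.16 and -0.05 ± 0.14. Leaving out 1 library left the group lower in each of the 4 cases, with a mean of -0.08 without Y41F library 1, -0.17 without WT library 1 and -0.44 without Y41F library 2. The size of the change thus leaned on Y41F library 1. Between libraries of 1 group (library 2 over library 1) the mean differed by -0.15 in WT and 0.35 in Y41F. The Y41F libraries thus differed from each other by more than Y41F did from WT.

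Ribosomal protein genes were slightly lower as a group (131 tested, 113 with a fold change below 0, mean -0.08, median -0.09, camera adjusted p = 1.47e-04; adjusted p = 0.993 with an estimated correlation). None passed over all genes or adjusted over the list alone, and rpl301 and rps7 had -0.14 ± 0.14 and -0.10 ± 0.12. Without WT library 1 the mean was 0.01 and without Y41F library 2 -0.02, and both ended the call (camera adjusted p = 0.956 and 0.870), while it was -0.17 without WT library 2 and -0.15 without Y41F library 1. With library size as the only scaling the mean was -0.04 and the list was still called. Camera sets a list against all other genes, so a shift of all genes alike hardly alters its call. Between libraries 1 and 2 the mean differed by -0.18 in WT and -0.13 in Y41F (library 2 over library 1). Nuclear-encoded oxidative phosphorylation genes were also lower (38 tested, mean -0.10, median -0.11, camera adjusted p = 0.0013; adjusted p = 0.588 with an estimated correlation). None passed over all genes or adjusted over the list alone. The ATP synthase gene atp2 and the succinate dehydrogenase gene sdh1 had -0.16 ± 0.11 and -0.06 ± 0.11, and without Y41F library 2 the call was lost (camera adjusted p = 0.270). With library size as the only scaling the mean was -0.05. The list was still called, which again does not check the scaling.

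Tf2 retrotransposon genes were lower as a group (13 tested, mean -0.29, median -0.15, camera adjusted p = 1.47e-04; adjusted p = 0.700 with an estimated correlation). None was called over all genes, and Tf2-7 and Tf2-8 passed when adjusted over the list alone. The most abundant, Tf2-3 and Tf2-6, shared 1 set of counts and had -0.15 ± 0.17. In all, 10 of the 13 had the same counts as another gene, and with such genes merged, chosen after seeing the data, the mean was -0.09 and the call was lost (camera adjusted p = 0.129). Without WT library 2 the mean was 0.01, though the median was -0.14 and the list was still called lower (camera adjusted p = 1.70e-04), without Y41F library 1 it was -0.07 (camera adjusted p = 0.297) and without Y41F library 2 -0.77. With a filter at 10 CPM the mean was -0.44, and between libraries of 1 group (library 2 over library 1) it differed by 0.40 in WT and 0.66 in Y41F.

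All 10 genes of the auxotrophic marker list had fold changes below 0, and the list was lower (mean -0.14, median -0.12, camera adjusted p = 0.0139; adjusted p = 0.756 with an estimated correlation). None passed over all genes or adjusted over the list alone. Of these, 9 are biosynthetic genes, while any1, entered under its synonym can1, encodes an arrestin-related adaptor. Between libraries of 1 group (library 2 over library 1) the list differed by a mean of -0.13 (median -0.15) in WT and -0.06 (median -0.09) in Y41F. Without any1, left out after the values were seen, the list's mean log2 fold change was -0.12 and the call was lost (camera adjusted p = 0.0574). The values were -0.32 ± 0.11 for any1, -0.22 ± 0.10 for ade6, -0.15 ± 0.09 for his7, -0.14 ± 0.12 for his3, -0.13 ± 0.08 for arg3, -0.12 ± 0.12 for ade1, -0.12 ± 0.10 for ura5, -0.10 ± 0.11 for his2 and -0.03 ± 0.10 for both lys1 and leu1, of which lys1 and leu1 lay above 0 with library size as the only scaling and on the FPKM scale. Without WT library 1 or Y41F library 2 the list's mean was -0.07 and -0.11 and the call was lost (camera adjusted p = 0.316 and 0.367), and with library size as the only scaling it was -0.09.

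**Figure D2:**
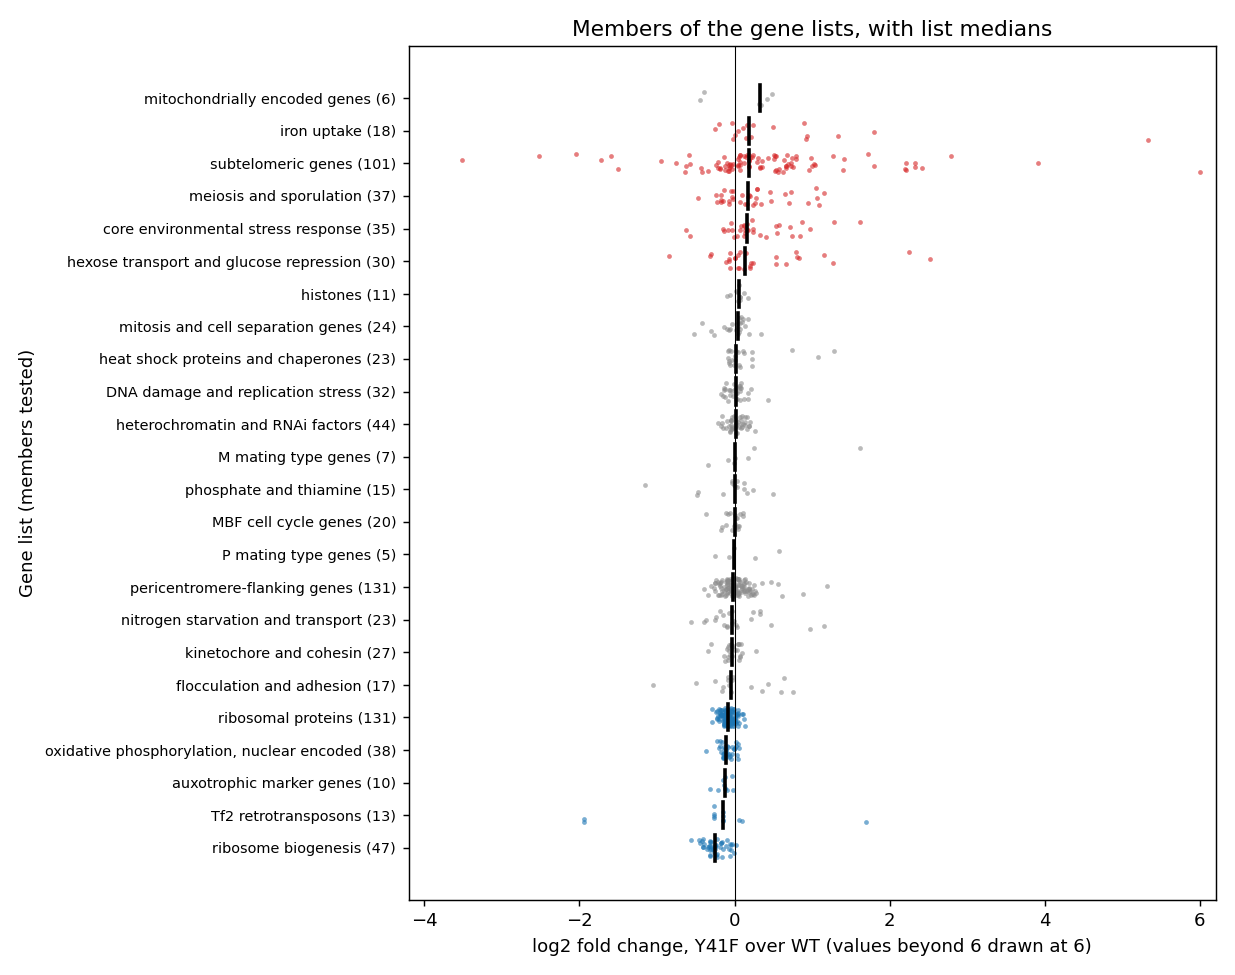
Log2 fold change (Y41F over WT) of each tested member of the 24 gene lists, as points, with a black line at each list's median and the number of members tested in brackets; red lists were called higher and blue lists lower by camera at a preset correlation, grey lists were not called. The ribosome biogenesis list has its median at -0.26, with 46 of 47 members below 0, and the subtelomeric list has its median at 0.18 with members spread widely on both sides.

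Camera thus called 10 of the 24 lists with the preset correlation, 5 higher and 5 lower, and 0 with an estimated correlation (lowest adjusted p 0.512). The estimate was 0.743 for ribosomal proteins, 0.558 for ribosome biogenesis, 0.509 for auxotrophic markers and 0.404 for Tf2, far above the preset 0.01. Members of these lists thus did not vary independently. It was 0.0417 for oxidative phosphorylation and between -0.0282 and 0.144 for the 5 higher lists. Fry, which tests whether a list's genes move one way, called 0 (lowest adjusted p 0.582), and its mixed test gave adjusted p between 0.0961 and 0.821.

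The lists not called include heterochromatin and RNAi factors, with a mean of 0.02 and a median of 0.02 over 44 genes (camera adjusted p = 0.960). The histone chaperone gene spt16 and the remodeller gene fft3 had -0.15 ± 0.09 and 0.13 ± 0.11. Pericentromere-flanking genes (131) had a mean of 0.02 and a median of -0.02, with the test's direction down (adjusted p = 0.969), and fba1 and sua1 had -0.17 ± 0.12 and -0.21 ± 0.16. Adjusted over the list alone, pun1 passed there. As the deposited lengths are coding lengths, noncoding transcripts near the centromeres were not examined. Kinetochore and cohesin genes (27) had a mean of -0.03 (adjusted p = 0.501), and bub1 and cnp3 had -0.14 ± 0.12 and -0.34 ± 0.10. DNA damage and replication stress genes (32) had a mean of 0.01 (adjusted p = 0.993), and cdc22 and suc22 had 0.02 ± 0.11 and 0.02 ± 0.09. MBF cell cycle genes (20) had a mean of -0.03 and a median of 0.00, on opposite sides of 0 (adjusted p = 0.626), and tos4 had 0.03 ± 0.13. Mitosis and cell separation genes (24) had a mean of -0.02 and a median of 0.04, with the test's direction down (adjusted p = 0.960), and adg2 and mid2 had -0.10 ± 0.16 and 0.18 ± 0.10.

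Heat shock proteins and chaperones (23) had a mean of 0.16 and a median of 0.02 (camera adjusted p = 0.233), and sks2 and ssa2 had -0.07 ± 0.12 and -0.03 ± 0.17, while ssa1, chosen after its values were seen, had 1.08 ± 0.23. That list was called higher without WT library 1 (mean 0.21, camera adjusted p = 0.0114) and without Y41F library 2 (mean 0.17, 0.00412). Nitrogen starvation and transport genes (23) had a mean of 0.05 and a median of -0.04, with the test's direction down (adjusted p = 0.960). Adjusted over that list alone, aat1 passed as lower and the dipeptide transporter gene dal51, chosen after its values were seen, as higher, at 0.97 ± 0.14, and inv1 and gaf1 had 0.23 ± 0.73 and -0.10 ± 0.10. Flocculation and adhesion genes (17) had a mean of 0.03, a median of -0.04 and the test's direction up (adjusted p = 0.987). Adjusted over the list alone, pfl3 passed as lower and the glucanase gene bgl2, chosen after its values were seen, as higher, at 0.64 ± 0.12, and pfl2 and gas2 had -0.15 ± 0.24 and 0.44 ± 0.22. Phosphate and thiamine genes (15) had a mean of -0.08 and a median of 0.01, with the test's direction down (adjusted p = 0.881), and plb1 and pho1 had 0.50 ± 0.22 and -0.48 ± 0.25. Each of these 2 values rested mostly on 1 library. For plb1 libraries 1 and 2 had 3623 and 2303 CPM in Y41F against 2075 and 2127 in WT. For pho1 they had 755 and 1299 in WT against 761 and 711 in Y41F. M mating type genes (7) had a mean of 0.23 and a median of 0.01 (adjusted p = 0.442), with mam3 at -0.09 ± 0.16 and mam2 at -0.01 ± 0.11. Their mean was 0.40 without WT library 1 and 0.16 without Y41F library 2. P mating type genes (5) had a mean of 0.10, a median of -0.01 and the test's direction up (adjusted p = 0.881), with sxa1 at 0.27 ± 0.12 and map3 at -0.01 ± 0.08. Mitochondrially encoded genes (6), all under 5 CPM in every library, had a mean of 0.12 (adjusted p = 0.895), with SPMIT.01 at 0.31 ± 0.35 and SPMIT.02 at -0.45 ± 0.50. Without WT library 1, flocculation and adhesion (mean -0.05), phosphate and thiamine (-0.14) and mitochondrially encoded genes (0.87) were called (camera adjusted p = 0.0278, 0.00757 and 0.0170). In the lists of this paragraph and the one before, no member was called over all genes.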

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

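Tests in this part were planned, apart from the merging of identical genes, the subtelomeric list by position within 100 kb and the marker list less any1, which were chosen after seeing the data. The count of 1 called gene held with DESeq2 size factors, library size only, no filter, a filter at 10 CPM and log2(FPKM + 0.1) or log2(FPKM + 5), and with identical genes merged. It was 2 with limma-voom, 3 on log2(FPKM + 1) and 2 on that scale without the filter, all higher and at least 2-fold. DESeq2's Wald test called 68 (62 higher, 6 lower, 18 at least 2-fold), for which the cause was not tested. The numbers 1 and 2 in the library names are not stated to mark a batch, so they do not establish pairs. With the number as a replicate block edgeR called 87 genes (77 higher, 10 lower, 27 at least 2-fold), 55 of them shared with DESeq2, 59.9% of the 599 genes at an unadjusted p under 0.05 were higher, and across genes the shift between the numbers correlated at r = 0.446 between WT and Y41F. Without 1 library, the count ranged from 0 to 197, the genes higher from 0 to 90, lower from 0 to 107 and at least 2-fold from 0 to 48. The lone library left in a group is then assumed to vary like the other group. Of 106 named genes, 31 reversed in some setting, 8 of them in a setting that keeps all libraries. The only gene edgeR called with all 4 libraries, yhb1, did not reverse. With library size as the only scaling, lys1 had 0.0200, leu1 0.0189, tpx1 0.0131, ssa2 0.0204, abc4 0.0433, mam2 0.0360, mde4 0.0138 and map3 0.0321, against values below 0 with TMM. On log2(FPKM + 1), with and without the filter, they had 0.0201, 0.0189, 0.0063, 0.0268, 0.0457, 0.0326, 0.0153 and 0.0321 in that order, with the pseudocount 0.1 they had 0.0202, 0.0189, 0.0063, 0.0268, 0.0464, 0.0332, 0.0155 and 0.0325 and with the pseudocount 5 they had 0.0197, 0.0187, 0.0063, 0.0268, 0.0429, 0.0304, 0.0145 and 0.0305. With the filter at 10 CPM abc4 had 0.0059. Ranges without 1 library that crossed 0 were hhf1 -0.2246 to 0.3241, hht1 -0.0236 to 0.258, hhf3 -0.0788 to 0.2155, hhf2 -0.0395 to 0.0847, lys1 -0.0629 to 0.0124, leu1 -0.0836 to 0.0313, tpx1 -0.1943 to 0.1205, rds1 -0.7911 to 0.8506, cdc22 -0.07 to 0.1089, pfl2 -0.396 to 0.1601, sks2 -0.1624 to 0.0211, ssa2 -0.2158 to 0.1843, tdh1 -0.0809 to 0.0955, pdc101 -0.1708 to 0.0663, htb1 -0.0158 to 0.1204, hta2 -0.1403 to 0.1802, abc4 -0.0512 to 0.0532, mam3 -0.3013 to 0.1106, mam2 -0.1191 to 0.0997, tos4 -0.0847 to 0.1564, mde4 -0.1305 to 0.0706, adg2 -0.2975 to 0.1225, inv1 -1.1741 to 1.0524, map3 -0.0323 to 0.0064, rps7 -0.1938 to 0.0038, nop56 -0.2011 to 0.0852, Tf2-6 -0.3953 to 0.0704, Tf2-3 -0.3953 to 0.0704, agl1 -3.4276 to 2.0377, fbp1 -1.2881 to 2.285 and hsp16 -0.0144 to 2.7266. With an estimated correlation or with fry, 0 lists were called against 10, at unchanged means (auxotrophic markers -0.1358, stress response 0.2833, hexose transport 0.3616, iron uptake 0.6721, meiosis 0.2430, oxidative phosphorylation -0.0958, ribosomal proteins -0.0837, ribosome biogenesis -0.2473, subtelomeric genes 0.4000, Tf2 -0.2873). Camera was not run on DESeq2's fit, which gives no list test. In the other settings with all 4 libraries camera called between 9 and 11 lists: meiosis lost its call on log2(FPKM + 5), with a mean of 0.1629, and Tf2 with identical genes merged, at -0.0876, where fewer distinct genes were tested, while heat shock proteins and chaperones gained one with the replicate block (0.1564, adjusted p = 0.00335). The marker list less any1 lost its call, at -0.1152. Library size only and log2(FPKM + 1) brought ribosomal proteins to -0.0355 and -0.0365, oxidative phosphorylation to -0.0496 and -0.0491 and the markers to -0.0882 and -0.0880, all still called. As camera sets a list against all other genes, these calls do not check the scaling. Subtelomeric genes by position within 50 kb had a mean of 0.53 and within 100 kb 0.43, both called. Without 1 library the list means ranged -0.1987 to -0.0667 for auxotrophic markers, 0.0584 to 0.5974 for stress response, -0.0169 to 0.0481 for DNA damage and replication stress, -0.048 to 0.1428 for flocculation and adhesion, 0.0042 to 0.0359 for heterochromatin and RNAi factors, -0.0321 to 0.1171 for histones, -0.067 to 0.0131 for MBF cell cycle genes, 0.1356 to 0.3192 for meiosis, -0.3737 to 0.8731 for mitochondrially encoded genes, -0.0698 to 0.0293 for mitosis and cell separation genes, -0.159 to 0.284 for nitrogen starvation and transport, -0.1117 to -0.0753 for oxidative phosphorylation, -0.1179 to 0.2724 for P mating type genes, -0.0128 to 0.0376 for pericentromere-flanking genes, -0.1401 to 0.0329 for phosphate and thiamine, -0.1691 to 0.0107 for ribosomal proteins and -0.7679 to 0.0141 for Tf2. Without WT library 1 flocculation and adhesion (-0.0480), mitochondrially encoded genes (0.8731) and phosphate and thiamine (-0.1401) were called too. Lists not called turned in direction of the test as follows: DNA damage with no filter (mean 0.0137) and the replicate block (0.0134); flocculation with library size only (0.0756), the filter at 10 CPM (-0.0311) and FPKM (0.0656 with and without the filter, 0.0776 and 0.0428 with the other pseudocounts). Mitosis turned with limma-voom (-0.0225), FPKM (0.0242 with and without the filter, 0.0244 and 0.0234) and fry (-0.0180), and nitrogen (0.0484) and pericentromere-flanking genes (0.0184) with fry. For these changes, too, the cause was not tested. In data simulated at this depth and spread edgeR recovered 86% of genes changed 2-fold but 40% of those changed 1.5-fold. Those data held 200 changed genes and no shift shared between libraries. The shares therefore do not show how many changed genes the test missed in the measured data.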

Other observations

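The test of growth state for the shift between libraries 1 and 2 and the leaving out of neighbouring pairs with identical counts were chosen after the results were seen. All genes and gene pairs named in this part were chosen after their values were seen, apart from those the naming rule gave.

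Several genes that respond to glucose and stress differed between libraries 1 and 2 more than between WT and Y41F. The alpha-glucosidase gene agl1 had 45.8 and 632 CPM in WT libraries 1 and 2, and 31.5 and 345 in Y41F libraries 1 and 2. The gluconeogenic gene fbp1 had 14.8 and 85.0 CPM in WT and 20.4 and 124 in Y41F, and the small heat shock gene hsp16 had 25.8 and 114 in WT and 69.4 and 273 in Y41F. The methyltransferase gene cmt2, a subtelomeric gene, had 3.05 and 7.03 CPM in WT and 18.3 and 133 in Y41F, so its log2 fold change of 3.91 ± 1.00 (SE, n = 2 per group) rested mostly on Y41F library 2, without which it was 1.86. The calcium signalling genes prz1, ncs1 and cmk1 had log2 fold changes of 0.84 ± 0.14, 0.87 ± 0.15 and 0.85 ± 0.15, with an edgeR adjusted p of 0.283 for each, and DESeq2 called all 3. A hypothesis that calcium signalling genes were higher in general was tested on 11 other such genes. Their mean was 0.02 (0.0234 ± 0.0409, SE over genes), which goes against a general rise but not against a rise of some of them. Of the 11, 7 lay above 0. The highest were pmc1 and pmr1, at 0.28 ± 0.08 and 0.24 ± 0.10, and the lowest was cam1, at -0.13 ± 0.09.

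Subtelomeric genes were higher in Y41F as a group by camera at the preset correlation, with a median log2 fold change of 0.18. With an estimated correlation they were not called (camera adjusted p = 0.512). A difference at 1 chromosome end cannot be told apart from one at all ends. Without the right end of chromosome II, the end with the highest mean (0.96 over 19 genes, with SPBCPT2R1.02 at its fitted 9.26), the mean was 0.271 ± 0.117 (SE over genes). This mean passed the limit set before the test for arguing against 1 end alone. Its SE, however, takes genes as independent, so the question was left open. The left end of chromosome II had a mean of 0.46, and the left and right ends of chromosome I had 0.12 and 0.13. Medians lay above 0 at each end (0.15 to 0.52). Without Y41F library 2 the mean of the whole list was -0.03. Noise of weakly expressed genes cannot be told apart: the median lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.179, but such lists assume that members vary independently, and this list also differed between libraries of 1 group, by a mean of 0.40 (median 0.22) between the Y41F libraries and 0.38 (median 0.08) between the WT libraries. Reads shared between near-identical copies cannot be told apart from a change of the group either. The 53 members whose expected counts, before rounding, were whole in all libraries had a mean of 0.258 ± 0.132 and a median of 0.14. The 48 others, among them SPBCPT2R1.02 at its fitted value, had a mean of 0.56 and a median of 0.38. A change in silent chromatin caused by the substitution may underlie the pattern but was not tested, and other differences between the strains stay open too.

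Neighbouring genes tended to differ in the same direction. Adjacent here means next to each other among genes that matched the annotation and had a mean of at least 5 CPM. An omitted gene may lie between the members of some pairs, also in the comparison for crossing reads below. Adjacent genes had a Spearman correlation of 0.0819 across 4850 pairs, or 0.081 without the 4 pairs whose members have identical counts. Without those, 32 adjacent pairs had both members at an unadjusted p under 0.05 with the same sign, 29 of them higher, against 12.3 on average in 1000 shuffled gene orders (highest 23; permutation p = 0.001, the smallest these shuffles can give). They include mal1 with ght4, ght4 with frp1, sul2 with yhb1, and SPCC417.09c with dal51, which in turn adjoins SPCC417.11c. Subtelomeric genes alone were argued against as the source, as the correlation without them was 0.0752, above the 99th percentile of shuffled orders (0.031). Reads that cross between adjacent genes remain a candidate explanation, since genes next but 1 to each other had a correlation of 0.0157, below the 99th percentile of 0.0343, and a difference that any pair of libraries would show cannot be told apart, because the correlation was 0.0497 within WT and 0.0401 within Y41F, too close to that between groups.

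Libraries with the same number shifted together in WT and Y41F. Sampling noise of low counts was argued against, because over the 3426 genes with a mean of at least 1000 counts the shifts correlated at r = 0.463. A difference in growth state between the cells of libraries 1 and 2 may underlie the shift: the core environmental stress response list lay higher in library 2 in both groups, by a mean of 0.49 in WT and 0.30 (0.3001) in Y41F on the log2 scale, but by medians of 0.21 and 0.05, so in Y41F a minority of its genes carried the shift. Ribosome biogenesis genes did not follow a single course, at -0.15 in WT and 0.35 in Y41F. No biological explanation from the design was tested, since the labels do not say what the numbers stand for, and genes are not independent replicates in these correlations.

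A hypothesis that the difference between Y41F and WT lay along the same axis as the shift between libraries 1 and 2 was tested across genes, and the Pearson correlation was -0.0513 (Spearman 0.0088), which goes against it as the whole cause across genes. For single lists it stays open, since 8 of the 10 called lists had a mean shift in both groups in the direction of their difference between Y41F and WT (5 of 10 by the median), a count made after the values were seen.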
